A study of Mus musculus with 3 samples.

How the data were processed

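Brain immune cells of 8 mice were measured in 1 pooled single-cell preparation, in which an RNA library, a library of 35 surface antibody tags and a library of hashtags (antibodies that carry a barcode for each brain) were sequenced. Per the labels, cells were enriched on a Percoll gradient of 70, 37 and 30% and captured with droplet chemistry version 3 from the 3 prime end. Per the labels, the upstream steps used Cell Ranger 3.1 and Seurat 3.1.1 with the mm10 mouse genome.

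The authors deposited 2 tables of RNA values, for metastasis-bearing and for naive brains, whose unit is the natural logarithm (ln) of 1 plus a depth-corrected UMI count (UMIs are barcoded RNA molecules) per gene and cell. This was checked on the values: the exponential minus 1 was whole, within a relative tolerance of 1e-06, for 29262479 nonzero values in the metastasis table and 9282424 in the naive table, which is 100% of each. The tables held 19208 and 17453 genes. The correction had been fitted separately in each table, so the same raw count can have different values in the 2 tables. The deposited cell metadata gave other units, namely raw UMIs, detected genes, hashtag UMIs and antibody tag UMIs per cell as plain counts, the hashtag margin, the mitochondrial percent, the authors' clusters and the authors' antibody gates. The hashtag and the genotype of each cell were read from the same metadata, which number brains as hashtags and name genotypes as heterozygous or homozygous. The deposited mitochondrial percent was 0 in all cells although 13 mitochondrial genes were in the tables, so it was recomputed from the corrected UMIs.

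Brains were the replicates, with 2 heterozygous and 2 homozygous brains in each table. Of 13455 deposited cells, 1138 barcodes stood in both tables and were left out of each, which left 11179 cells. All 9581 and 3874 cells of the 2 tables carried the authors' singlet label, which was given within the 4 hashtags of each table. No further call of droplets with more than 1 cell was made. Hashtags cannot show 2 cells of the same brain in a droplet, and whether the barcodes in both tables held more than 1 cell was not tested. Authors' clusters were named by hand from fixed marker lists, with the help of the genes that set each cluster apart. A cluster of few UMIs stayed unnamed in each table, as did 2 naive clusters with markers of several myeloid or antigen-presenting cell types. A small metastasis-table cluster with Krt8 and Wfdc2 was joined to the Krt8-high class although 0 of its 10 most distinct genes were on the lists; 7 of its cells were used. In metastasis-bearing brains a named class was tested for expression where every brain had at least 20 cells. In naive brains microglia-like cells alone were tested.

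For each brain and class, corrected UMIs were summed, scaled to 1000000 (CPM) and transformed as log2 of CPM plus 10. Genes with a mean above 10 CPM were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), separately in each table, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Genotype effects were homozygous minus heterozygous. The interaction was the difference between the 2 within-table genotype effects, which leaves out a scale difference that acts alike on both genotypes of a table. Metastasis effects on expression were not tested, because the 2 tables carry separate corrections; levels are given side by side. Gene lists, 20 of pathways and 30 of cell type markers, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a kind within a contrast. Class shares were compared with two-sided exact permutation tests (scipy 1.17.1). Intervals for shares of single brains are 95% Wilson intervals, those for shares of cells with a UMI are exact Clopper-Pearson intervals, and both cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

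The steps were tested on simulated data with 200 changed genes and 5 runs per comparison. The simulated noise followed the trend of the spread over the mean, with no gene-specific spread and no correlation between genes. Recovery in the real data can therefore be lower. With a 2-fold change, 86.6 to 100% of the changed genes were recovered, and with a 4-fold change 100%. Unchanged genes made up 3.4 to 5.7% of the calls.

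The lists, the tests of the planned comparisons and the rule for named genes were set before the data were examined. List tests on the interaction and some tests of explanations were chosen afterwards. By that rule Cx3cr1 comes first, then Cxcl10, Vsir and Cd274. The 10 genes with the largest rise and the 10 with the largest fall among those past the threshold without overlap between the genotypes follow. Further named genes are, for each called pathway list, the 4 members with the smallest p, and, where under 5 genes passed, the 10 with the smallest p. In the classes other than microglia-like cells, at most 5 called genes in each direction are named. Not every gene that the rule picks is printed.

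Alternatives tried were limma without a trend, a filter of 1 CPM, a pseudocount of 1 CPM, means of per-cell values, each brain left out in turn, cells with at most 10% mitochondrial UMIs and at least 500 genes, and CD45-type classes as the denominator. Alternatives added after seeing the data were all deposited cells, a hashtag margin of at least 1, median-ratio scaling, the authors' microglia gate, and cells of 5000 to 15000 raw UMIs. That gate was the authors' microglia label in naive brains. In metastasis-bearing brains it was a subset that the authors only numbered, read here as microglia. Surface antibody levels were not analysed here because the values per antibody were not in the tables used. Classes with too few cells per brain, and clusters that stayed unnamed, were left out of the expression tests. Naive T/NK-like cells, with 44 to 75 cells per brain, were also left out. Genotype effects in classes other than microglia-like cells were planned for metastasis-bearing brains alone.

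Raw UMIs in the cells used ranged from 37044426 to 196416973 per metastasis-bearing brain and from 4304699 to 17527285 per naive brain. These totals mix classes whose shares differ between brains. In metastasis-bearing brains the medians per cell were 96635 to 116929 in Krt8-high cells and 4773 to 5518.5 in T-like cells. In microglia-like cells they were 7850.5 to 12596, highest in homozygous brain 1. In the smallest tested group of microglia-like cells, 1 brain contributed 35 cells.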

Results

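Single-cell RNA was measured in immune cells enriched from the brains of 8 female mice aged 2 to 3 months. In 4 mice E0771 mammary tumour cells had been injected into the carotid artery about 2 weeks earlier (metastasis-bearing brains), and 4 were naive. In each state 2 brains were heterozygous and 2 homozygous for loss of Cx3cr1, the receptor for the chemokine fractalkine, which microglia (the resident macrophages of the brain) carry in large amounts. After barcodes found in both tables were left out, 8443 cells of metastasis-bearing and 2736 cells of naive brains were used. The heterozygous metastasis-bearing brains gave 1354 and 2610 cells, with medians of 8199.5 and 7823.5 raw UMIs per cell. The homozygous metastasis-bearing brains gave 2925 and 1554 cells, with medians of 71585 and 19767.5. These medians mix cell classes. T-like cells alone had medians of 4773 and 5431.5 raw UMIs in the heterozygous and 5518.5 and 5450 in the homozygous metastasis-bearing brains. Naive brains gave 957 and 537 heterozygous and 337 and 905 homozygous cells, with medians between 6181 and 7096 raw UMIs. The series title names Cxcl10 in myeloid cells of the brain, and the genotype comparisons ask how cells differ when Cx3cr1 is lost.

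Clusters were named by marker genes. Microglia-like cells carried P2ry12, Fcrls and Tmem119, and monocyte/macrophage-like cells carried Ccr2, Lyz2 and Ms4a4c. T-like, NK-like, B-like and vascular-like clusters carried Cd3g, Ncr1, Cd79a and Cldn5. A cluster high in Krt8, Wfdc2 and genes of dividing cells had a Ptprc UMI in 1.6% of its cells in the metastasis table and a median of 102993 raw UMIs. It is called Krt8-high here, because no label names the tumour cells among the clusters.

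Krt8-high cells made up 12.8% ± 6.29 (SD, n = 2) of the cells in heterozygous and 49.0% ± 9.70 (n = 2) in homozygous metastasis-bearing brains. Microglia-like cells made up 17.2% ± 16.5 and 2.58% ± 0.462 in the same brains, with 28.8 and 5.52% in the heterozygous ones; the difference of -14.6 percentage points was -2.94 without heterozygous brain 1. Vascular-like cells made up 9.25% ± 7.50 and 3.49% ± 0.249, a difference of -5.76 points that was -0.454 without the same brain. B-like cells made up 1.796% ± 0.765 and 0.328% ± 0.174, and choroid plexus-like cells 0.732% ± 0.114 and 0.184% ± 0.0782. In these 5 of 10 classes the brains of the 2 genotypes did not overlap, where chance gives 33.3%. The shares of a brain add up to the whole, so a higher Krt8-high share lowers the others and the classes are not independent. Among CD45-type classes alone, the microglia-like shares of the 2 genotypes overlapped. The homozygous brains held 6 and 7 B-like and 7 and 2 choroid plexus-like cells. The exact permutation p was 0.333 in each, the smallest that 2 against 2 brains allow, so the design could not pass 0.05. Shares overlapped between genotypes for monocyte/macrophage-like cells (21.9% ± 9.77 against 19.9% ± 6.32), T-like cells (17.3% ± 13.8 against 9.12% ± 1.58) and NK-like cells (9.05% ± 8.93 against 7.06% ± 0.752), each with an exact permutation p of 1. Among CD45-type classes alone, homozygous minus heterozygous turned from -1.98 to 13.9 percentage points for monocyte/macrophage-like cells and from -1.99 to 4.22 for NK-like cells. In naive brains microglia-like cells made up 47.0% ± 6.68 of heterozygous and 42.0% ± 2.33 of homozygous cells (exact permutation p = 0.667, n = 2 each), and the difference of -5.02 points was -0.296 without heterozygous brain 1 and -9.75 without heterozygous brain 2.

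Between the states, every naive brain had a higher share of microglia-like cells than every metastasis-bearing brain, with 44.5% ± 5.01 (SD, n = 4) against 9.87% ± 12.7 (n = 4). Krt8-high cells went the other way, with 4.60% ± 1.46 in naive and 30.9% ± 21.96 in metastasis-bearing brains. Both differences had an exact permutation p of 0.0286, the smallest that 4 against 4 brains allow, and an adjusted p of 0.0857 over 6 classes, so neither passed after adjustment. With all deposited cells, barcodes in both tables included, the brains of the states overlapped in both classes: Krt8-high cells made up 10.2% ± 1.19 in naive (lowest 8.97) and 29.6% ± 20.9 in metastasis-bearing brains (lowest 7.89; exact permutation p = 0.143), and microglia-like cells 33.8% ± 5.62 and 10.6% ± 12.5 (exact permutation p = 0.0571). T-like and NK-like cells together made up 9.93% ± 2.67 and 21.3% ± 14.4 (exact permutation p = 0.0857, adjusted p = 0.171); the difference of 11.3 points was 4.28 without metastasis-bearing heterozygous brain 2 and 21.9 among CD45-type classes alone (exact permutation p = 0.0286).

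**Figure D1:**
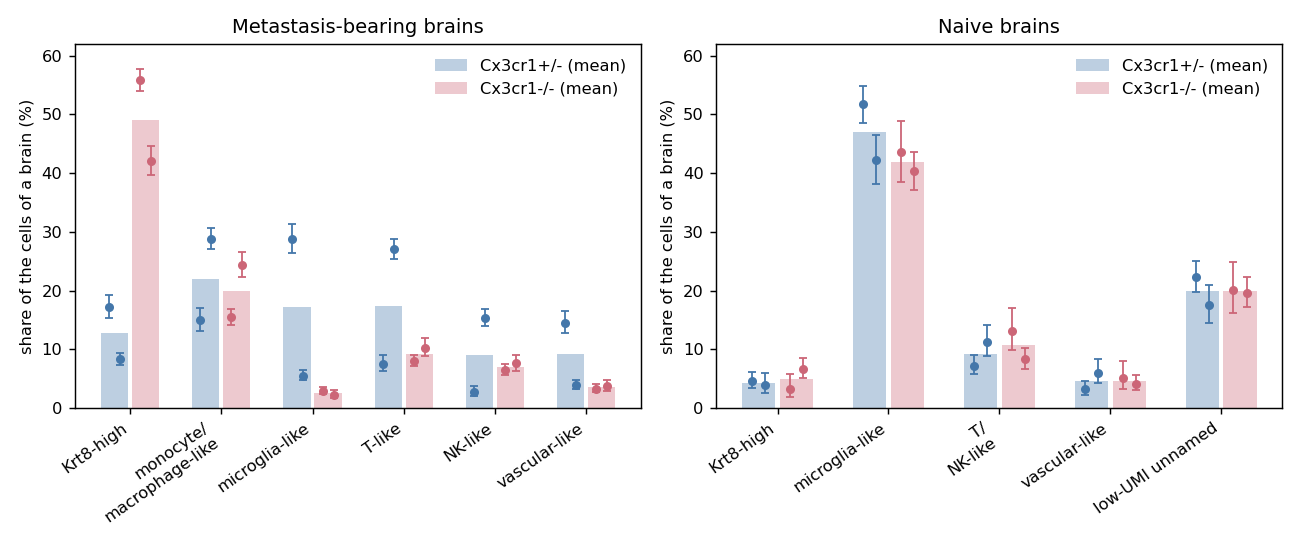
Share of each cell class in percent of the cells of a brain, by state and genotype: bars give the mean of 2 brains, points the brains with 95% Wilson intervals. Krt8-high cells made up 42.1 and 55.9% of the cells in the homozygous metastasis-bearing brains and 17.2 and 8.31% in the heterozygous ones.

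In microglia-like cells of metastasis-bearing brains, homozygous loss of Cx3cr1 went with higher expression of Cxcl10 and of antiviral interferon-response genes. Cx3cr1 itself fell from 1414 ± 71.3 to 72.5 ± 58.0 CPM (SD, n = 2 each; log2 fold change -4.31, SE 0.42, adjusted p = 0.0176). Cxcl10, a chemokine that draws T and NK cells carrying Cxcr3, rose from 302 ± 64.4 to 1072 ± 16.2 CPM (log2 fold change 1.81, SE 0.16, adjusted p = 0.0165). The largest rise was in Rsad2, an interferon-induced antiviral enzyme, from 19.4 ± 3.22 to 199 ± 13.6 CPM (log2 fold change 2.83, SE 0.18, adjusted p = 0.00244). Ifit2, which binds viral RNA, and Ifi204 and Ifi207, members of a family of interferon-induced DNA sensors, rose by 2.23, 1.66 and 1.91 on the log2 scale. The checkpoint ligands Vsir (log2 fold change -0.39, adjusted p = 0.545) and Cd274 (0.42, adjusted p = 0.757) did not pass. In all, 5 genes rose and 1 fell among 7374 tested with limma, 635 had an unadjusted p under 0.05, and 40.6% did not overlap between genotypes against 33.3% by chance.

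Among the interferon-stimulated genes in these cells, all 43 tested members had a positive log2 fold change, with a median of 0.95. Between the 2 heterozygous brains the median difference over the list was 0.45 (brain 2 minus brain 1), and between the homozygous ones -0.09. Rsad2, Ifit2 and Ifi204 rose over all genes tested, and 30 members rose when adjusted over the list alone; Oasl1 (1.72, adjusted p = 0.0614) was the next member by p. The list was called by camera at the preset correlation (adjusted p = 3.51e-34), and its adjusted p = 0.410 with an estimated correlation. Among 12 chemokines Cxcl10 rose, 4 members rose when adjusted over the list alone, and the log2 fold changes of Ccl12, Ccl2 and Ccl7 were 1.16, 0.97 and 0.72 (list adjusted p = 1.4e-05, and adjusted p = 0.410 with an estimated correlation). The 4 markers of monocyte-derived macrophages had a median log2 fold change of 0.63, and 2 rose when adjusted over the list alone (list adjusted p = 0.00241). The 6 cycling markers had a median of 0.71 (list adjusted p = 0.00241) and the 4 monocyte markers of 0.83, of which 2 rose over the list alone (list adjusted p = 0.207). Each of these 3 lists had an adjusted p = 0.456 with an estimated correlation. The homozygous brains were also those with the most Krt8-high cells.

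Homeostatic microglia genes leaned the other way: 27 of the 29 had a negative log2 fold change, with a median of -0.32, and P2ry12, Cst3, Gpr34 and Maf stood at -0.64, -0.65, -0.47 and -0.61. None of them fell over all genes and 2 fell when adjusted over the list alone (list adjusted p = 6.6e-09, and adjusted p = 0.397 with an estimated correlation). Disease-associated microglia genes, a set that microglia switch on around damage, had a median of 0.38 in 27 genes, led by Axl (1.26), Lilrb4a (1.31), Ctsb (0.55) and Lpl (1.38), with 4 genes past the threshold when adjusted over the list alone and an adjusted p = 0.532 with an estimated correlation. Phagocytosis and lysosome genes had a median of 0.22 in 27 genes, led by Cd36 (1.60) and Ctsc (0.67), with 6 past the threshold over the list alone and an adjusted p = 0.454 with an estimated correlation. The 25 oxidative phosphorylation genes, among them Atp5k, Ndufa2, Uqcrq and Cox5b, all had positive values (median 0.26), as did 13 of 15 glycolysis genes, among them Gapdh, Eno1, Pkm and Pfkl (median 0.19); each list had an adjusted p = 0.410 with an estimated correlation. Proliferation genes (median 0.53 in 22 genes, with Mcm3, Tpx2, Mcm5 and Tubb5 first) and cytotoxic effector genes (median 0.63 in 8 genes, with Gzmb, Gzma, Cst7 and Nkg7 first) had 0 members past the limma threshold over the list alone and adjusted p = 0.532 and 0.533 with an estimated correlation.

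MHC class II presentation genes had a median log2 fold change of -0.83 in 9 genes, with H2-Eb1 at -2.65, H2-Aa at -2.59, H2-Ab1 at -1.99 and H2-Ob at -0.83. H2-Eb1 stood at 200.1 ± 186 CPM in the heterozygous brains, a spread nearly as large as its mean, and the 3 mature dendritic cell markers had a median of -0.88 in the same comparison. Over the list alone 3 class II genes fell, and the list had an adjusted p = 0.532 with an estimated correlation. MHC class I presentation genes, with Calr, Erap1, B2m and Psmb10 first, had a median of 0.24, which turned to -0.05 without heterozygous brain 1 (adjusted p = 0.587 with an estimated correlation). Immediate early and dissociation stress genes had a median of -0.24 in 25 genes, with Rgs1 at 0.76 and Ier5, Zfp36 and Junb at -0.49, -0.34 and -0.35 (adjusted p = 0.532 with an estimated correlation). The TGF-beta and interleukin 10 pathway, with Tgfbr1, Il10ra, Smad7 and Socs3 first, had a median of -0.16 in 12 genes (adjusted p = 0.410 with an estimated correlation).

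In cells of 5000 to 15000 raw UMIs limma called 0 genes in microglia-like cells of metastasis-bearing brains, with 372 at an unadjusted p under 0.05, and the log2 fold change of Cxcl10 was 1.94 there with an adjusted p of 0.866, in a range from 3.35e-17 to 0.866 over 14 alternatives. Without the trend in the variance 1 gene passed limma, with all deposited cells 2 and with the authors' microglia gate 10.

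**Figure D2:**
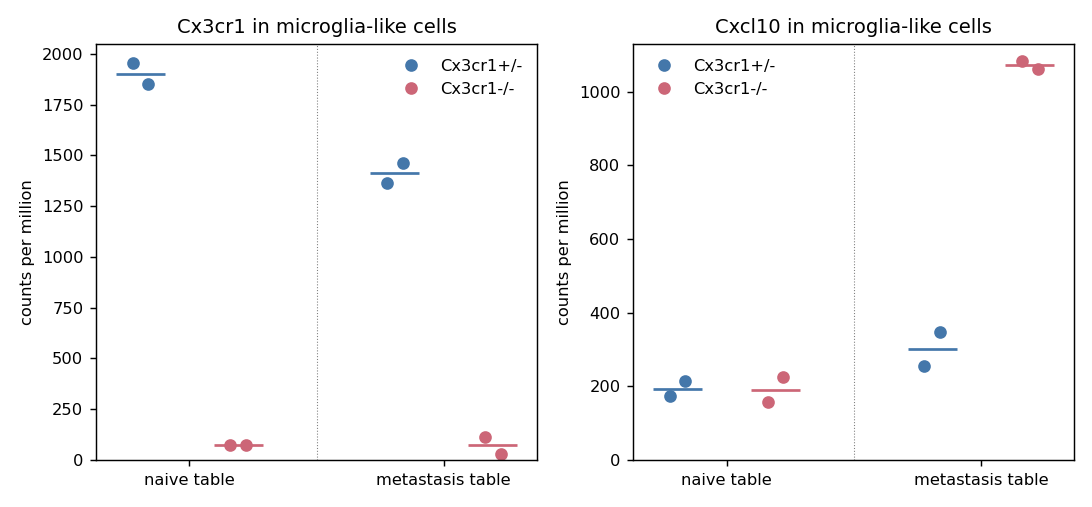
CPM of Cx3cr1 and Cxcl10 in microglia-like cells, by genotype and state, with a point per brain and a line at the mean. Cxcl10 stood at 1072 ± 16.2 CPM in homozygous and 302 ± 64.4 in heterozygous metastasis-bearing brains, and at 191 ± 48.0 and 194 ± 28.1 in naive brains, where values come from a separate correction.

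**Figure D3:**
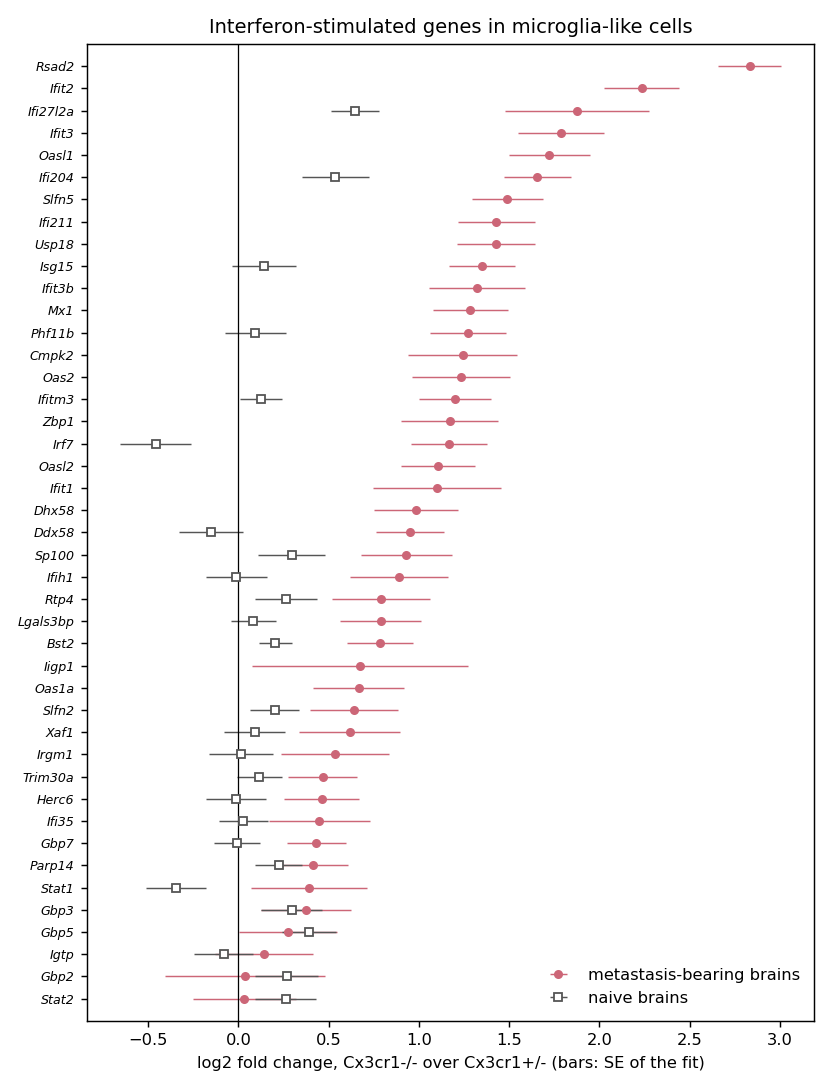
Log2 fold changes (homozygous minus heterozygous) of the interferon-stimulated genes in microglia-like cells, by state, with the SE of the fit as bars. The median was 0.95 over 43 genes in metastasis-bearing brains and 0.12 over 26 genes in naive brains. The gene sets differ, and over the 26 genes tested in both states the median difference was 0.53.

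In microglia-like cells of naive brains, homozygous loss of Cx3cr1 went with higher levels of some inflammatory cytokine genes, among them Tnf, and lower levels of a few homeostatic genes, while Cxcl10 hardly moved. Neither list was called as a whole with an estimated correlation. Cx3cr1 fell from 1902 ± 71.2 to 73.5 ± 3.01 CPM (SD, n = 2 each; log2 fold change -4.52, SE 0.08, adjusted p = 5.17e-27). Cxcl10 stood at 194 ± 28.1 and 191 ± 48.0 CPM (log2 fold change -0.04, adjusted p = 0.966), and Vsir and Cd274 at log2 fold changes of 0.00 and -0.01. Tnf, a central inflammatory cytokine, rose from 254 ± 56.4 to 452 ± 62.4 CPM (log2 fold change 0.81, SE 0.11, adjusted p = 3.22e-05). Tcim rose from 39.6 ± 5.23 to 106 ± 1.46 CPM (log2 fold change 1.23, SE 0.12, adjusted p = 3.28e-07), and the metalloprotease Adamts1 from 474 ± 16.6 to 777 ± 22.8 CPM. Other large rises included the cystine transporter Slc7a11 (0.96), Emp3 (0.85), Gch1 (0.79), the acid sensor Gpr65 (0.69), the nuclear receptor Nr4a1 (0.66) and the interferon-induced gene Ifi27l2a (0.64). Fcrls, a marker of resident microglia, fell from 1675 ± 187 to 1120.0 ± 18.5 CPM (log2 fold change -0.57, SE 0.08, adjusted p = 5.75e-05). Gm13889 fell by 1.52 on the log2 scale, and Clec4a3, Lag3, Ccl9, Zbtb20, Serpine2, Socs3 and Cd63 fell by 0.61, 0.57, 0.51, 0.47, 0.45, 0.40 and 0.38. In all, 31 genes rose and 13 fell among 7693 tested with limma, 655 had an unadjusted p under 0.05, and 37.2% did not overlap between genotypes against 33.3% by chance.

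Of 19 NF-kappaB and inflammatory cytokine genes in naive microglia-like cells, Tnf, Il1a, Il1b, Bcl2a1b, Nlrp3 and Cd14 rose, and 8 rose when adjusted over the list alone (median 0.17, list adjusted p = 1.05e-07, and adjusted p = 0.615 with an estimated correlation). Il1b stood at 0.00 with the authors' microglia gate. The 3 neutrophil markers had a median of 0.47, of which S100a9 and S100a8 rose over the list alone (list adjusted p = 0.0613, and adjusted p = 0.479 with an estimated correlation). Among 25 immediate early and dissociation stress genes, Klf2, Klf6 and Nr4a1 rose, with Klf4 at 0.28, and 5 rose when adjusted over the list alone (median 0.09, adjusted p = 0.697 with an estimated correlation). Among 29 homeostatic genes Fcrls and Crybb1 fell, with Gpr34 and Maf at -0.28 and -0.26, and 5 fell when adjusted over the list alone (median -0.07, adjusted p = 0.615 with an estimated correlation). Of 11 chemokines Ccl9 fell; Cxcl2 and Cxcl16 stood at 0.53 and 0.44 and Ccl4 at -0.46. Over that list alone 2 genes rose and 4 fell, its median of -0.29 became -0.0021 without homozygous brain 1, and its adjusted p = 0.615 with an estimated correlation. The 3 T cell exhaustion genes tested were Lag3, which fell, Havcr2 (-0.20) and Entpd1 (-0.07), with an adjusted p = 0.615 with an estimated correlation. Mitochondrially encoded genes, with mt-Nd4l, mt-Nd1, mt-Nd2 and mt-Atp8 first, had a median of -0.06 (camera adjusted p = 0.703 with an estimated correlation). Their median turned to 0.04 with the authors' microglia gate. The 26 interferon-stimulated genes had a median of 0.12 and were not called (adjusted p = 0.0538, and adjusted p = 0.703 with an estimated correlation). RNA of red blood cells stood apart in 1 brain: Hbb-bs was at 0.809 and 498 CPM in the heterozygous brains and at 0 and 1.43 in the homozygous ones. The 3 erythroid markers had a median of -1.57 (list adjusted p = 1.89e-06, and adjusted p = 0.349 with an estimated correlation). In microglia-like cells the median, the mean or the test differed in sign for complement, disease-associated, proliferation and TGF-beta genes in naive brains and for T cell exhaustion genes and checkpoint ligands in metastasis-bearing brains; none of these lists was called.

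Of the 44 calls in naive microglia-like cells the count fell to 2 without the trend and 7 with the authors' microglia gate. It was 23 with all deposited cells and 25 in cells of 5000 to 15000 raw UMIs. With median-ratio scaling 16 genes were higher and 15 lower, 29 of them among the 44.

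**Figure D4:**
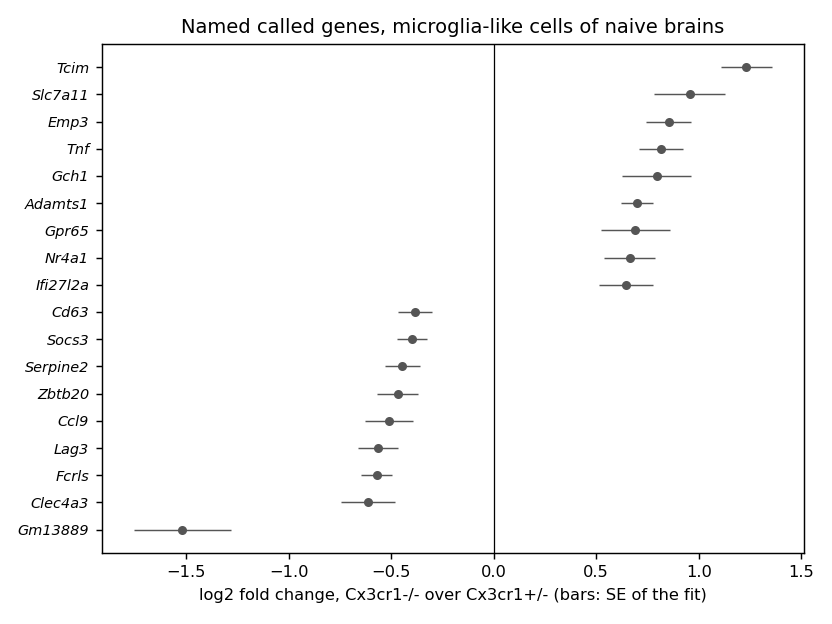
Log2 fold changes (homozygous minus heterozygous, bars give the SE of the fit) of 18 called genes named for the size of their change, other than Cx3cr1, in microglia-like cells of naive brains. They range from 1.23 for Tcim to -1.52 for Gm13889, with Tnf at 0.81 and Fcrls at -0.57.

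The interaction asked whether the genotype effect in microglia-like cells differed between metastasis-bearing and naive brains. It did for 1 gene of 7065: the genotype effect on Cxcl10 was higher by 1.85 on the log2 scale in metastasis-bearing brains (SE 0.24, adjusted p = 0.0406), from 2 brains per genotype and state. No gene passed in the other direction with limma, and 596 had an unadjusted p under 0.05. The next genes by p, none of which passed, were Mknk2, Marcksl1, Ms4a6c, Cited2, Samd4b, AY036118, Hist1h2ae, Ctsb and Irf7. Of the 6 genes called in metastasis-bearing brains 3 were tested in both states, so the interaction was not tested for the others. Of the genes called in either state and tested in both, Cx3cr1 alone was called in both. Its loss defines the genotype, so setting this overlap against the 0.0187 expected from independent lists does not measure a shared response. Gene lists were tested on the interaction after the data had been seen. Interferon-stimulated genes had a median difference of 0.53 over 26 genes (adjusted p = 1.28e-12, and adjusted p = 0.187 with an estimated correlation). Chemokines had a median difference of 0.80 over 11 genes (adjusted p = 6.23e-08, and adjusted p = 0.134 with an estimated correlation). NF-kappaB genes had -0.32 over 19 genes and homeostatic genes -0.21 over 29 (adjusted p = 0.187 and 0.134 with an estimated correlation). At the preset correlation 12 lists were called and with an estimated correlation 0, by camera. The Cxcl10 call was lost without the trend, with a pseudocount of 1 CPM, with a hashtag margin of at least 1, with all deposited cells and in cells of 5000 to 15000 raw UMIs. It was also lost without metastasis-bearing heterozygous brain 1 (log2 difference 1.63), without naive heterozygous brain 1 (1.99) or 2 (1.70), and without naive homozygous brain 1 (1.60) or 2 (2.09), with adjusted p from 0.00146 to 0.809 over 18 alternatives. Leaving out a naive brain gave 0 genes each time, and leaving out metastasis-bearing heterozygous brain 1 or 2 or homozygous brain 1 or 2 gave 4, 6, 313 and 173.

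Levels in heterozygous microglia-like cells of the 2 states are given side by side and were not tested, because the states carry separate corrections. The interferon-stimulated genes had a median log2 ratio of metastasis-bearing to naive of 0.87, and 25 of the 26 were higher in both metastasis-bearing brains than in both naive brains (n = 2 each), where chance gives 33.3% without overlap in either direction. Lack of overlap was common in other lists too, so the count alone does not set this list apart. All 25 oxidative phosphorylation genes were higher. Of 25 immediate early genes 17 were lower and 3 higher, and of 14 checkpoint ligands 5 were lower and 2 higher. Homeostatic microglia genes had a median log2 ratio of -0.45, and 27 of the 29 were lower in both metastasis-bearing brains; P2ry12, a receptor by which microglia sense nucleotides, stood at 2094 ± 14.6 CPM in naive and 1298 ± 31.4 in metastasis-bearing brains. Tnf stood at 254 ± 56.4 and 1029 ± 62.4 CPM, and the interferon-induced membrane gene Ifitm3 at 81.1 ± 10.3 and 316 ± 85.4. The 11 chemokines had a median log2 ratio of 0.87 and the 21 MHC class I genes of 0.63. In 147 microglia-like droplets that stood in both tables with the same raw totals, median log2 ratios between the tables lay between -0.19 and 0.21 for the 19 lists. Oxidative phosphorylation genes, at 0.41 between states, had 0.19 in those droplets.

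In other cells of metastasis-bearing brains the interferon-stimulated genes also stood higher in homozygous brains. Their median log2 fold change was 0.43 in monocyte/macrophage-like cells (39 of 46 genes positive), 0.31 in T-like cells (38 of 45), 0.57 in NK-like cells (41 of 42), 0.64 in vascular-like cells (42 of 42) and 0.53 in Krt8-high cells (28 of 34), with 2 brains per genotype. No member rose over all genes tested with limma in these 5 classes, and 31, 11, 21, 19 and 16 rose when adjusted over the list alone. The list was called in each class at the preset correlation, and its adjusted p was 0.200, 0.430, 0.281, 0.424 and 0.656 with an estimated correlation. Mitochondrially encoded genes stood lower in the same classes, with medians of -0.16, -0.16, -0.05, -0.41 and -0.24, and 0, 7, 0, 10 and 5 of them fell when adjusted over the list alone. Their list was called at the preset correlation in each class but NK-like cells, and its adjusted p was 0.711, 0.370, 0.645, 0.424 and 0.656 with an estimated correlation. Whether the interferon effects differ from the one in microglia-like cells was not tested.

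In NK-like cells Cxcl10 rose from 171 ± 16.3 to 529 ± 138 CPM (SD, n = 2 each; log2 fold change 1.55, SE 0.16, adjusted p = 0.0224). Heterozygous brain 1 gave 37 of these cells. Monocyte/macrophage-like cells of the same brains held more Cxcl10, as given below, and whether their RNA reached NK-like droplets was not tested. The chemokine Ccl4 rose from 1586 ± 202 to 2851 ± 160 CPM (0.85, adjusted p = 0.0224), and Cd69, an early activation marker, from 113 ± 23.4 to 313 ± 53.8 CPM (1.39, adjusted p = 0.0309). These 3 genes rose and 0 fell among 6299 tested with limma, and 254 had an unadjusted p under 0.05. The next genes by p did not pass: Klf2 (-0.62), Zfp36 (0.65), Gadd45b (0.84), Icam1 (1.40), Dusp1 (0.57), Nfkbia (1.03) and Gzmb (0.80). NF-kappaB genes had a median of 0.23 in 13 genes and cytotoxic effector genes, with Gzmb, Ifng, Gzma and Prf1 first, 0.12 in 12 genes; 5 and 3 of them rose when adjusted over the list alone. Immediate early and dissociation stress genes, with Klf2, Zfp36, Dusp1 and Nr4a1 first, had a median of 0.12 in 22 genes, and 5 rose and 1 fell over the list alone (list adjusted p = 0.00336). Each of these lists had an adjusted p = 0.281 with an estimated correlation. Proliferation genes had a median of -0.27 in 19 genes and cycling markers of -0.67 in 6 (adjusted p = 0.626 and 0.404 with an estimated correlation). The depth correction added UMIs here: 46 NK-like droplets in both tables held 274187 raw and 526385 corrected UMIs in the metastasis table, and Rhox5, found in 99.7% of Krt8-high cells, had a UMI in 69.6% of these droplets in that table and in 10.9% in the naive table. Without the trend 0 genes passed, and leaving out heterozygous brain 1 or 2 gave 58 and 920 genes.

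In monocyte/macrophage-like cells Gzma, a granule protease of killer cells, rose from 61.4 ± 3.48 to 186 ± 12.4 CPM (SD, n = 2 each; log2 fold change 1.46, SE 0.11, adjusted p = 0.0392), the 1 call among 6980 genes tested with limma, of which 535 had an unadjusted p under 0.05. NK-like cells of the same brains held 7119 ± 960 and 9468 ± 908 CPM of Gzma. Cx3cr1 had a log2 fold change of -2.19 (adjusted p = 0.170) and Cxcl10, at 2740.5 ± 584 and 3256 ± 53.2 CPM, of 0.26 (adjusted p = 0.790). Further genes by p, none past the threshold, were Cd36 (-1.10), Serpinb8 (0.89), Gm19951 (1.06), Cd300e (1.25), Fabp4 (-0.89), Ifit2 (0.81), Usp18 (0.83) and Ifi206 (0.74). MHC class II genes, with H2-DMb2, Cd74, H2-Aa and H2-Ab1 first, had a median of -0.61 in 11 genes, of which 10 fell when adjusted over the list alone (adjusted p = 0.711 with an estimated correlation), and the 7 markers of type 2 conventional dendritic cells had a median of -0.32. Markers of type 1 conventional (-0.34 in 4 genes) and mature dendritic cells (-0.51 in 4) were also negative and those of monocytes positive (0.38 in 8), and these 4 marker lists had an adjusted p = 0.461 with an estimated correlation. Non-classical monocyte markers had a median of 0.26 in 6 genes, cycling markers of -0.48 in 6 and regulatory T cell markers of -0.48 in 4, each with an adjusted p = 0.545 with an estimated correlation, and plasmacytoid dendritic cell markers of -0.18 in 7 (adjusted p = 0.735 with an estimated correlation). Proliferation genes (-0.33 in 14 genes), homeostatic microglia genes (-0.28 in 26), immediate early genes (-0.20 in 24), NF-kappaB genes (-0.19 in 23) and T cell exhaustion genes (-0.37 in 8) were also called at the preset correlation, with adjusted p from 0.711 to 0.713 with an estimated correlation. The Gzma call was lost without the trend, with all deposited cells, with median-ratio scaling and without homozygous brain 2 (log2 fold change 1.39), and leaving out heterozygous brain 1 or 2 or homozygous brain 1 gave 148, 230 and 5 genes.

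In T-like cells limma called 0 of 6524 genes, with 297 at an unadjusted p under 0.05. The smallest p belonged to Cd69 (0.74), Isg15 (0.67), Furin (0.90), Rgs1 (0.49), Ly6c2 (0.49), Ifi203 (0.43), Usp18 (0.81), H2-Aa (-1.15), Fos (0.46) and H2-Ab1 (-1.25), none past the threshold. Cxcl10 had a log2 fold change of 0.14 (adjusted p = 0.974), which turned to -0.31 without heterozygous brain 2 and was 0.59 without heterozygous brain 1. The 5 gamma-delta T cell markers had a median of 1.19, all 5 past the threshold over the list alone, with an adjusted p = 0.836 with an estimated correlation. MHC class II genes, with H2-Aa, H2-Ab1, H2-Eb1 and Cd74 first, had a median of -0.97 in 6 genes, of which 5 fell over the list alone, and naive and memory T cell genes, with Klf2, S1pr1, Bach2 and Lef1 first, had -0.33 in 10 genes, of which 2 fell; each list had an adjusted p = 0.394 with an estimated correlation. T cell exhaustion genes, with Pdcd1, Tox, Havcr2 and Rgs16 first, had a median of 0.26 in 13 genes, of which 0 passed limma over the list alone. Immediate early genes had a median of 0.15 in 22 genes, of which 5 rose and 1 fell over the list alone, and NF-kappaB genes of 0.08 in 14, of which 2 rose. These 3 lists had an adjusted p = 0.430 with an estimated correlation. Leaving out heterozygous brain 1 or 2 gave 67 and 240 genes.

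In vascular-like cells limma called 0 of 8896 genes, with 918 at an unadjusted p under 0.05. Cxcl10 stood at 217 ± 117 and 519 ± 72.9 CPM (SD, n = 2 each; log2 fold change 1.31, adjusted p = 0.318) and Cx3cr1 at a log2 fold change of -0.87. The smallest p belonged to Gadd45g (-1.53), Pdlim1 (1.81), Upp1 (1.96), Tspan6 (1.66), Plpp2 (1.67), Vim (0.82), Cd34 (0.88), Fam167b (1.06), Ifit3 (1.07) and Ifit1 (0.90), none past the threshold. Proliferation genes, with Top2a, H2afz, Pclaf and Birc5 first, had positive values in 23 of 23 genes (median 0.65), and 12 rose when adjusted over the list alone (adjusted p = 0.424 with an estimated correlation). The 6 cycling markers had a median of 1.14, and 6 rose over the list alone (adjusted p = 0.785 with an estimated correlation). Among markers of other cell types, 3 mammary tumour markers had a median of 0.57 and 6 mural cell markers of -0.57, each with an adjusted p = 0.785 with an estimated correlation. Rhox5 had a UMI in 36.8% of 68 droplets, vascular-like by their metastasis-table cluster, in that table. In the naive table it had a UMI in 30.9% of the same droplets. The homozygous brains held more Krt8-high cells. Mitochondrially encoded genes were negative in 13 of 13 (median -0.41), and 10 fell when adjusted over the list alone (adjusted p = 0.424 with an estimated correlation). Immediate early genes, with Ier3, Zfp36, Hspa1a and Jun first, had a median of -0.60 in 25 genes, of which 9 fell when adjusted over the list alone (adjusted p = 0.554 with an estimated correlation). MHC class II genes had a median of -0.90 in 7 genes and NF-kappaB genes of -0.26 in 17 (adjusted p = 0.424 and 0.507 with an estimated correlation). Without homozygous brain 1 or 2 there were 5 and 169 genes, and with the limits on mitochondrial share and genes per cell 2.

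In Krt8-high cells Tmsb4x fell from 217 ± 46.3 to 46.4 ± 9.57 CPM (SD, n = 2 each; log2 fold change -2.01, SE 0.18, adjusted p = 0.00984) and Mgp from 20.8 ± 1.05 to 1.51 ± 0.235 CPM (-1.42, SE 0.11, adjusted p = 0.00856). Tmsb4x stood at 17157 ± 1333 CPM in monocyte/macrophage-like cells and Mgp at 3874 ± 1846 CPM in vascular-like cells of the heterozygous brains. These 2 genes fell and 0 rose among 8011 tested with limma, and 480 had an unadjusted p under 0.05. The next by p did not pass: Acta2 (1.18), Srgn (-1.08), Oas1a (0.96), Ifi35 (0.82), Selenbp1 (1.01), C2 (0.79), Ifi44 (1.01) and Lgals3bp (0.91); Cxcl10 stood at 0.18 (adjusted p = 0.904). Proliferation genes had a median of -0.17 in 24 genes, glycolysis genes of 0.12 in 16 and phagocytosis and lysosome genes of 0.16 in 16, each with an adjusted p = 0.656 with an estimated correlation. With all deposited cells and with a hashtag margin of at least 1 there were 0 calls, and leaving out heterozygous brain 1 or 2 or homozygous brain 1 or 2 gave 2150, 242, 22 and 12 genes.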

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

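The tests of Krt8-high RNA, of Krt8-high cell numbers and of hashtag UMIs in naive Krt8-high cells were chosen after the result was seen. The tests of depth, of monocyte/macrophage RNA and of mixed droplets were written before theirs. The window of raw UMIs in the depth test was itself added after the data had been seen. The genotype effect on Cxcl10 in microglia-like cells differed between the states by 1.85 on the log2 scale, in the test of the difference itself. In data outside the comparisons, 136 Krt8-high cells carried a naive hashtag and 1138 barcodes stood in both tables. Of these barcodes 64.6% had the same genotype in both tables, and 92.8% had more hashtag UMIs in the metastasis table, with a median of 1781.5 against 41.

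Interferon-stimulated genes, with Cxcl10 among the genes that rose beside them, stood higher in homozygous microglia-like cells of metastasis-bearing brains, with a median log2 fold change of 0.95. RNA of Krt8-high cells is argued against as the whole cause. The 14 genes at least 20-fold higher in those cells showed a median share of -0.432% of Krt8-high RNA (quartiles -0.917 and 3.94). The interferon-stimulated genes would need 83.1% (quartiles 34.1 and 128). A part stays open, because the depth correction can shift such marker genes. Rhox5 had a UMI in 23.1% of 147 droplets, microglia-like by their metastasis-table cluster, in that table and in 10.2% in the naive table. RNA of monocyte/macrophage-like cells is argued against as the whole cause, since the 30 marker genes showed a median share of 3.03% (quartiles 0.954 and 7.23) where the interferon-stimulated genes would need 16.4% (quartiles 11.1 and 23.9). Depth cannot be told apart. In cells of 5000 to 15000 raw UMIs the median was 0.683, above the bound set beforehand, but its quartiles of 0.21 and 0.91 span that bound. Homozygous brain 1, the deepest, had 0.27 against 0.89 in homozygous brain 2. The 2 heterozygous brains differed there by a median of 0.61 (brain 2 minus brain 1), close to the 0.683 between genotypes. The number of Krt8-high cells and the genotype cannot be told apart either, because the lowest homozygous share was 42.1% and the highest heterozygous share 17.2%. Within the genotypes the values went opposite ways. Heterozygous brains 1 and 2 had Krt8-high shares of 17.2 and 8.31%, and brain 2 minus brain 1 had a median of 0.45 over the list. Homozygous brains 1 and 2 had shares of 55.9 and 42.1%, and a median of -0.09. An effect of the genotype itself stays open and untested apart from depth and the number of Krt8-high cells.

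Krt8-high cells also carried hashtags of naive brains, into which, per the labels, no tumour cells had been injected. Droplets that held both a Krt8-high and a microglial cell cannot be told apart: 21.3% (29 of 136, exact interval 14.8 to 29.2) had UMIs of at least 3 of the 10 microglia markers, against 100% of naive microglia-like cells and 3.94% of Krt8-high cells in the metastasis table. The interval spans the bound of 25% set beforehand, and the correction left a median of 7.25 UMIs per 100 raw UMIs in these cells, against 103 in naive microglia-like cells, so it would shrink the RNA of a second cell as well. A candidate explanation is that cells of metastasis-bearing brains were assigned to a naive hashtag: these cells had a median of 50.5 hashtag UMIs in the naive table, against 119.5 in naive microglia-like cells, and 266 Krt8-high barcodes found in both tables had 49.0 there and 594 in the metastasis table. The design gives no biological explanation for them, and none was tested.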

How the results depend on the processing

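Alternatives chosen after the data were seen were all deposited cells, the hashtag margin, median-ratio scaling, the authors' microglia gate, cells of 5000 to 15000 raw UMIs, cell quality outside the planned comparisons, and list tests on the interaction. Over the alternatives, 535 values for 39 called genes by class kept their sign except 1, and 380 stayed past the threshold. These counts include the fits with 1 brain left out. Genes named for a large rise or fall could not turn sign there, because they were picked for brains without overlap between genotypes. Of 3045 values for genes not called, 34 turned sign and 257 passed. Cx3cr1 in naive microglia-like cells stayed past the threshold in 14 of 14 alternatives (-4.68 to -3.91) and in metastasis-bearing brains in 12 of 14 (-5.10 to -2.57), Cxcl10 there in 11 of 14 (1.49 to 2.26), and the Cxcl10 interaction in 8 of 18 (1.42 to 2.09). The interferon list kept a positive median in metastasis-bearing brains (0.68 to 1.20, called in 14 of 15), in naive brains (0.01 to 0.22, called in 5 of 15) and in the interaction (0.26 to 0.86, called in 18 of 19). Counts of calls are given with the reported count first. Without the trend, calls in microglia-like cells went from 6 to 1 in metastasis-bearing and from 44 to 2 in naive brains, from 1 to 0 in monocyte/macrophage-like and from 3 to 0 in NK-like cells, and from 1 to 0 for the interaction. With all deposited cells they were 2 and 23 in microglia-like cells of the 2 states, 0 in monocyte/macrophage-like, 11 in NK-like and 0 in Krt8-high cells (2 reported); the interaction kept a count of 1 but with another gene. With the authors' microglia gate they were 10 and 7, and in cells of 5000 to 15000 raw UMIs 0 and 25, with 0 for the interaction. A filter of 1 CPM gave 1 in T-like cells (0 reported), 15 in NK-like cells and 3 for the interaction. A pseudocount of 1 CPM gave 0 for the interaction, a hashtag margin of at least 1 gave 0 there and 0 in Krt8-high cells, median-ratio scaling gave 0 in monocyte/macrophage-like cells, and cell quality gave 2 in vascular-like cells (0 reported). Median-ratio scaling split the naive calls into 16 higher and 15 lower, against 31 and 13, with 29 genes shared. With an estimated correlation 0 lists were called by camera in metastasis-bearing brains, in naive brains and for the interaction, against 13, 6 and 12. The authors' gate turned the mitochondrial list in naive brains to 0.042 and Il1b there to -0.0013. With CD45-type classes as the denominator the genotype difference in shares turned to 13.9 points for monocyte/macrophage-like and 4.22 for NK-like cells, and with all deposited cells the difference between states in microglia-like cells was -23.3 points (-34.6 reported), and that in Krt8-high cells 19.4 (26.3 reported). The cause was not tested for these changes.

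Leaving out 1 brain leaves a group of 1, which is assumed to vary like the other, so more genes can pass because the spread within that group is no longer counted. The counts then ranged from 36 to 88 and from 24 to 56 in microglia-like cells of metastasis-bearing and naive brains, from 0 to 230 in monocyte/macrophage-like, 0 to 240 in T-like, 3 to 920 in NK-like, 0 to 169 in vascular-like and 12 to 2150 in Krt8-high cells. For the interaction they ranged from 0 (each naive brain) to 313, with 4, 6, 313 and 173 without metastasis-bearing heterozygous brain 1 or 2 or homozygous brain 1 or 2. Lists called in metastasis-bearing brains ranged from 7 to 14. Medians ranged from -0.048 to 0.44 (MHC class I, metastasis-bearing), -0.15 to 0.40 (MHC class I, interaction), -0.52 to -0.0021 (chemokines, naive) and -0.15 to 0.0095 (mitochondrial, naive), and Cxcl10 in T-like cells from -0.31 to 0.59. Genotype differences in shares ranged from -8.89 to 4.93 points (monocyte/macrophage-like), -17.9 to 1.58 (T-like), -8.30 to 4.33 (NK-like), -26.2 to -2.94 (microglia-like, metastasis-bearing), -11.1 to -0.454 (vascular-like), -9.75 to -0.296 (microglia-like, naive) and -0.990 to 2.38 (Krt8-high, naive). Not run were DESeq2, planned for raw counts only, where limma without a trend took its place because these counts are depth-corrected, scaling without TMM and a fit of the contrast's brains alone, which the reported fit already is, a class definition by its largest cluster, since the microglia-like class was 1 cluster, metastasis effects on expression and their versions by genotype, since the states carry separate corrections, surface protein levels, and classes without enough cells in the window of raw UMIs. No paired analysis was possible because the hashtag numbers mark different mice in every group and pair none of them. With a simulated 2-fold change, recovery was lowest in NK-like cells, at 86.6%, and 93.4% in microglia-like cells of metastasis-bearing and 100% of naive brains. The simulated noise held no gene-specific spread, so these values can overstate recovery in the real data. The smallest groups were 37 NK-like cells with 191228 raw UMIs and 35 microglia-like cells with 341102.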

Other observations

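The test of free RNA and the reporter genes below were chosen after their values were seen; the tests of wrongly assigned cells and of the depth correction were written before. The tables hold values for EGFP and mCherry, and the labels used here name no reporter allele. EGFP was found in microglia-like cells of every brain: in naive brains 26.9% of 1234 cells had a UMI (exact interval 24.45 to 29.5, median of 7197 raw UMIs per cell) and in metastasis-bearing brains 30.7% of 654 cells (27.2 to 34.4, median of 8470). In naive T/NK-like cells 0.806% had an EGFP UMI (2 of 248 cells, exact interval 0.10 to 2.88, median of 5375.5), and in T-like cells of metastasis-bearing brains 0.4996% (6 of 1201, exact interval 0.18 to 1.08, median of 5409). The log2 fold change of EGFP between genotypes was 0.57 in naive (adjusted p = 0.0659) and 0.86 in metastasis-bearing microglia-like cells (adjusted p = 0.341), neither past the threshold. mCherry had a UMI in 5.59% of Krt8-high cells of metastasis-bearing brains (153 of 2739, exact interval 4.76 to 6.51, median of 102993 raw UMIs). It had a UMI in 0 of 654 microglia-like cells (median of 8470 raw UMIs), which allows up to 0.56%, and in 0 of 1786 monocyte/macrophage-like cells, which allows up to 0.21%. All of these are corrected UMIs. The limits are on cells with a corrected UMI and not on cells that carry the transcript, since even Krt8-high cells seldom had one. The correction acted unlike in the classes. In homozygous brain 1, Krt8-high cells held 181054379 raw and 20324304 corrected UMIs, and microglia-like cells 1383940 and 1065773.

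Cx3cr1 UMIs remained in homozygous microglia-like cells of naive brains, where 34.2% of 512 cells had one (exact interval 30.1 to 38.5, median of 7457.5 raw UMIs) against 99.9% of 722 heterozygous cells. Heterozygous cells assigned to a homozygous brain are argued against, since 3 homozygous cells reached 6 UMIs, the 5th percentile of heterozygous cells, and 90.7% of the level was left without them. UMIs added by the depth correction to shallow cells are argued against as the whole cause, since 27.7% of the shallower cells had a UMI and 40.6% of the deeper ones, with exact intervals of 22.3 to 33.7 and 34.6 to 46.9. A part stays open, because the shallower cells, at a median of 6055 raw UMIs, lay near the 6574.5 of all naive cells used. The levels of the shallower and deeper cells were alike, at 73.7 and 71.6 CPM. Free RNA is argued against as the whole cause, since 6.72% of homozygous T/NK-like cells had a UMI (8 of 119, exact interval 2.95 to 12.8, median of 5943 raw UMIs). Transcripts from the modified allele stay open and untested.

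Counted over all deposited cells, barcodes in both tables included, the authors' metadata placed 252 of 432 naive cells that carry its label for border-associated macrophages in the Krt8-high cluster.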
